A study of Rattus norvegicus with 12 samples.

How the data were processed

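Liver RNA from 12 male Sprague Dawley rats, 9 weeks old at the end of feeding, was measured on an Affymetrix rat expression array, 1 array per rat. Each array holds probe sets, which are groups of short probes aimed at one transcript. Per the labels' protocols, total RNA was taken from liver kept in a preservative, and 100 ng of it was turned into biotin-labelled cRNA with a kit that copies transcripts from their 3-prime end. The rats ate a purified control diet, the same diet with 0.1% wakame powder (the low group) or with 1% wakame powder (the high group) for 28 days. Wakame is an edible brown seaweed. Each diet had 4 arrays, numbered as in the labels, and every array was of a separate animal. Per the series' design text, each diet was fed to 6 rats kept 3 to a cage, so diet and cage cannot be told apart.

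The authors deposited one table of log2 values, with 1 column per array and 31099 probe sets. The log2 scale was inferred from the values, which run from 3.15 to 14.6, and is not stated in the sources used here. R 2.7.2 is named in the submitters' processing notes. The background correction, the normalization between arrays and the summarisation of probes into probe sets are not given in the sources used here. The median of each of the 12 arrays was 6.59 log2, which follows from the many flat values described below and does not show whether the varying values were normalized. No scanner files were used here, so no probe-level background or detection call stands behind any value, and the number of arrays limits the precision.

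Of the 31099 probe sets, 57 are control probe sets of the manufacturer and were left out of the tests. Among the other 31042, 27802 (89.6%) had a standard deviation (SD) over the 12 arrays of at most 0.01 log2 and are called flat here. The SD was below 1e-06 in 27627 of them, and 5695 had the same value on all 12 arrays. The remaining 3240 probe sets are called varying. A flat value is not evidence that the RNA level did not differ, since it is unknown how these values were made.

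Gene symbols came from the platform's annotation table, which can be old, with no symbol taken from a probe set listed under several. Of the 31099 probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had no gene named here, with control probe sets counted among these. The single symbols stood for 14217 genes, of which 2301 had a varying probe set. For 20764 of the single-symbol probe sets the gene identifier was in a RefSeq gene table of the rat assembly GRCr8, and the symbol was the same in all of them. The identifiers of the other 68 were not found there. The same table served to find list members under older symbols. The deposited table names no genome build, so no coordinates are given.

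The analysis fixed before the data were examined used limma 3.58.1 in R 4.3.3 on the deposited log2 values of all 31042 probe sets, with no further normalization and no filter. A mean per diet was fitted to all 12 arrays, so that the diets shared one estimate of the spread, and the moderated variances followed a trend with mean level. The comparisons were high against control, low against control and high against low, and an F-test asked for any difference among the 3 diets. Adjusted p is the Benjamini-Hochberg value over the probe sets tested, with a threshold of 0.05. This fit is called the planned fit. Most of its calls were changes below 1e-06 log2 in flat probe sets, which is the size of a rounding step.

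The same fit was therefore repeated on the 3240 varying probe sets alone. This restriction was chosen after the data were seen and after counts had been made at SD limits of 0.01, 0.05 and 0.1, each with and without the trend. The limit of 0.01 gives the most calls of the 3 in the comparison of high with control. It was kept because only 175 probe sets lie between an SD of 1e-06 and 0.01. In the report, rose, fell and changed refer to an adjusted p under 0.05 in this fit of varying probe sets, and the counts of the planned fit stand beside it. Where a change is given as a value ± SE, the value is the difference of mean log2 values, SE is its standard error in that fit and n is 4 arrays per diet.

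The genes named follow a rule fixed in advance. In each comparison it takes, among probe sets with 1 symbol that pass the threshold and whose 2 groups do not overlap, the 12 largest rises and the 12 largest falls, with 1 probe set per gene. Where fewer than 10 pass, it adds those with the smallest unadjusted p up to 10, as values that did not pass. It also takes up to 4 members of each called gene list, up to 2 of a list that was not called, and 27 genes fixed by name. The rule was applied to both fits. Genes picked only through flat probe sets are given as counts.

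The gene lists, 32 in all, were written before the data were examined. They cover fatty acid oxidation, other PPARalpha targets and ketogenesis, fatty acid and triglyceride synthesis, cholesterol biosynthesis, bile acid synthesis and sterol export, lipoproteins, gluconeogenesis, glycolysis and glycogen, thyroid hormone responsive genes, amino acid catabolism and the urea cycle, cytochrome P450s, phase II and NRF2 target genes, acute phase and inflammation, interferon response, unfolded protein response and heat shock, the circadian clock, growth hormone dependent and sex-biased genes, the cell cycle, oxidative phosphorylation, ribosomal proteins, the proteasome, metal handling and extracellular matrix. The other lists are markers of hepatocytes, Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes, lymphocytes, neutrophils and mast cells, erythroid cells, and adipose, muscle and pancreas. Some genes are in several lists. A list was tested with limma's camera at a preset correlation between genes of 0.01. The brightest single-symbol probe set per gene was used, where at least 5 members were measured. Among varying genes it was the brightest varying probe set, even where a flat one was brighter, and at least 5 members had to vary. Each call is set beside camera with an estimated correlation and beside fry, which asks whether the members move, on balance, one way without comparing them with other genes. Adjustment was over the lists tested in one comparison. A member said to pass adjusted over the list alone was adjusted over that list's varying members in one comparison. This does not account for the number of lists and comparisons searched. The same values also decide whether the list is called, so such a pass is weak support.

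A simulation of high against control, with 200 probe sets per run changed by known amounts in 5 runs, checked the steps. Over the 3240 varying probe sets, the fit recovered 44.2% of changes of 0.5 log2, 77.0% of changes of 1 log2 and 96.1% of changes of 2 log2, and 4.74% of its calls were false. Over all 31042 probe sets it recovered 24.5%, 58.2% and 88.5% of the same sizes, with 5.01% false. With no change put in, the 5 runs gave 0 calls over all probe sets and 1 over the varying ones (limma, adjusted p under 0.05). The simulated genes were independent and their noise was continuous, so neither correlated genes nor rounding steps were simulated.

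Alternatives were set in advance for the scale (16 added before log2), another normalization, a filter on dim probe sets, 1 probe set per gene, the variance moderation, array weights, the replicate number as a block, the arrays in the fit, the threshold, the set test and leaving out each array. Other splits of the arrays into groups of the same sizes were refitted, all 35 for 2 groups and 100 drawn for 3. For the correlation of fold changes, 100 random regroupings of the deviations from the diet means were drawn. Regroupings that kept a diet's arrays together were redrawn (5), a step added after it was seen that they force the correlation to −1 or 1. Single measures were compared by two-sided exact permutation tests, whose smallest possible p with 4 against 4 arrays is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.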

Results

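To ask how wakame in the diet relates to gene expression in the liver, as the series' title states, liver RNA was compared among rats fed a control diet, a diet with 0.1% wakame powder and a diet with 1% wakame powder for 28 days. Each diet was represented by 4 rats and 4 arrays. Of the 31042 probe sets tested, 27802 held almost the same value on all 12 arrays and are called flat, and 3240 varied. On these 3240, arrays of one diet correlated with each other at 0.911 to 0.961, and no pair of arrays held identical values. The first principal component took 25.0% of the variance. It averaged −13.36 ± 5.55 in control, 2.01 ± 10.45 in low and 11.35 ± 5.60 in high (SD, n = 4), which separated high from control by an exact permutation test (p = 0.0286, the smallest possible). The exact p was 0.0571 for low against control and 0.143 for high against low. The difference between the 3-prime and 5-prime probe sets of Actb, a sign of RNA integrity, was 2.31 ± 0.13 log2 in control, 2.25 ± 0.15 in low and 2.38 ± 0.07 in high. For Gapdh it was 1.05 ± 0.01, 1.08 ± 0.10 and 1.21 ± 0.16. None of the 6 exact tests of these differences passed (two-sided, unadjusted p from 0.143 to 0.629).

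The comparison of the 1% diet with control asks what the larger dose changed. Bcl6, a transcriptional repressor that growth hormone lowers in liver, rose by 5.21 ± 0.77 log2 (SE, n = 4 per diet, adjusted p = 0.0152), from 6.22 ± 0.48 to 11.44 ± 0.88 (SD), and lay higher in 4 of 4 rats than in any control. Nr1d1, the clock repressor REV-ERBalpha, rose by 1.98 ± 0.33 (adjusted p = 0.0262). Hacl1, a peroxisomal lyase that shortens branched and hydroxylated fatty acids, rose by 1.62 ± 0.35 (adjusted p = 0.0491). Onecut1, the hepatocyte transcription factor HNF6, fell by 3.17 ± 0.54 (adjusted p = 0.0268), and its second probe set fell by 2.10 ± 0.35. Socs2, a feedback inhibitor of growth hormone signalling, fell by 1.33 ± 0.27 (adjusted p = 0.0472). These calls come from the fit on varying probe sets, and in the planned fit of all probe sets the adjusted p of Bcl6, Nr1d1, Hacl1, Onecut1 and Socs2 were 0.176, 0.227, 0.297, 0.229 and 0.258. With each of the 8 arrays left out in turn, Hacl1 passed in 0 of 8 fits (limma, adjusted p from 0.0623 to 0.150), Socs2 in 1 (without high 1), and Nr1d1 and Onecut1 in 3 each (without control 3, high 1 and high 3). Bcl6 passed in 6, missing without control 4 and high 2 (highest 0.0761). The control means of Bcl6 and Nr1d1, 6.22 and 6.51, lay below the arrays' median of 6.59, and no background was available, so their sizes are lower bounds if those signals are background.

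Other genes that rose with the 1% diet included Jade1, a chromatin-associated factor, by 1.18 log2, Sh3bp5 by 1.17, the actin-binding Ablim3 by 1.05, Pald1 by 1.01 and Hycc2 by 0.97. Baiap2 and Baiap2l1, which link the membrane to actin, rose by 0.87 and 0.71, the repressor Foxp1 by 0.83 and Shld2, of a DNA repair complex, by 0.69. Among genes that fell, Rsrp1 was at −1.73, the iron-sulfur protein Cisd2 at −1.02, the Wnt receptor Fzd1 at −0.89, Cystm1 at −0.87 and the apoptosis inhibitor Birc2 at −0.83. Hacd3, of long-chain fatty acid elongation, was at −0.67, Pank3, of coenzyme A synthesis, at −0.63, the chaperone Hsp90ab1 at −0.59, Zfp68 at −0.49 and Krcc1 at −0.47. For all genes of this paragraph the adjusted p lay between 0.0096 and 0.0491. Brighter second probe sets of Cisd2, Hacd3, Rsrp1, Pank3, Zfp68 and Hsp90ab1 were at −0.14, −0.40, −0.56, −0.02, −0.26 and −0.36, the brightest of Krcc1 was flat and a dimmer one of Jade1 was at 0.18, so the sizes for these genes depended on the probe set. Dimmer probe sets of Foxp1 were at 0.70 and 0.44. With each array left out in turn, Hycc2 passed in 8 of 8 fits, Ablim3 in 7 (not without control 2) and Baiap2 and Rsrp1 in 4, and the other genes of this paragraph in at most 2. Ablim3 in control, at 6.24, also lay below the arrays' median. Single arrays stood apart from the rest of their diet for Onecut1, Sh3bp5, Birc2, Hacd3, Pank3, Zfp68 and Krcc1.

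**Figure D1:**
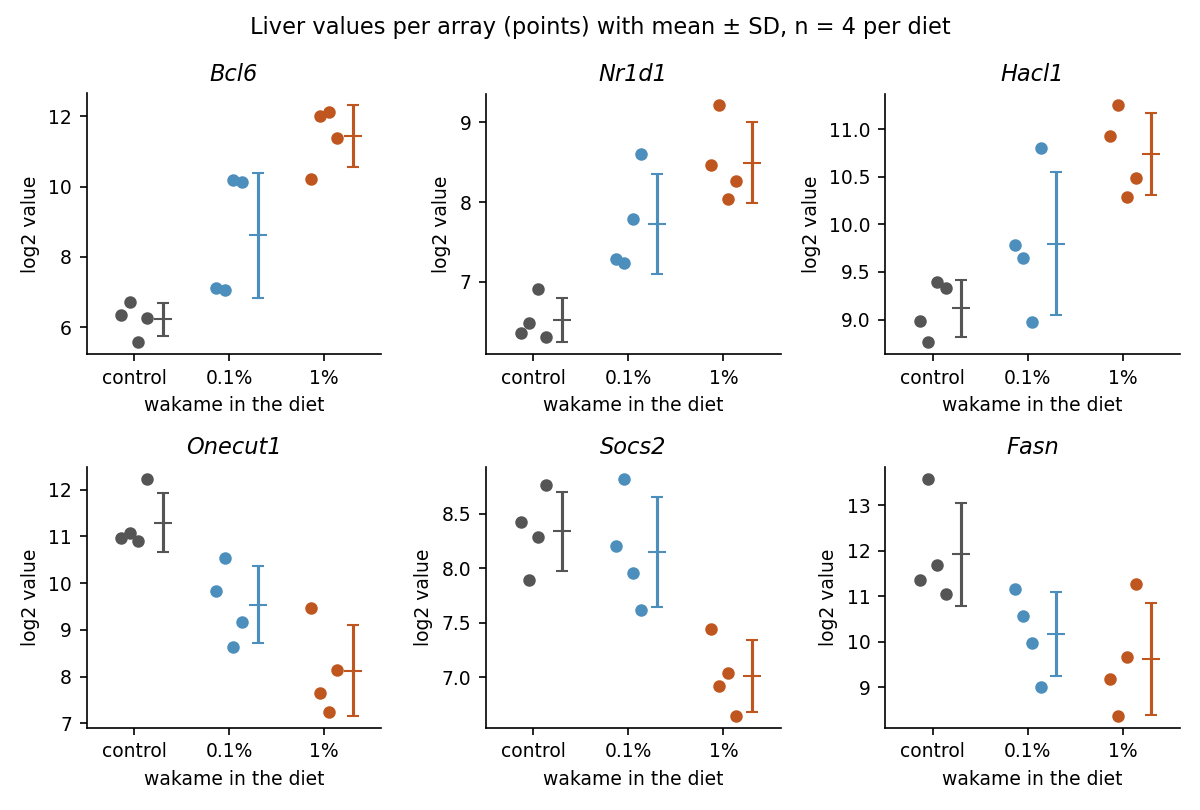
Log2 values of 6 genes on each of the 12 arrays (points) with the mean and SD per diet (bar), n = 4. Bcl6 rose from a mean of 6.22 in control to 11.44 with 1% wakame and Onecut1 fell from 11.30 to 8.13, while Fasn did not pass the threshold over all varying probe sets.

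In total 54 of 3240 varying probe sets changed between 1% wakame and control, 28 up and 26 down, by 0.30 to 5.21 log2. Of these, 35 carried 1 symbol, for 34 genes, 1 carried several and 18 had no gene named here. The diets did not overlap in any of the 54, and in 365 of all 3240 (11.3%), where chance gives 2.86%. The planned fit over 31042 probe sets called 9, of which 6 changed by less than 1e-06 log2. The other 3 fell, namely Asap2, a GTPase-activating protein, by 0.45 ± 0.05 (adjusted p = 0.0190), and 2 probe sets with no gene named here. Of the 10 genes the naming rule took from the planned fit, 7 were such flat changes, and Hycc2 (0.97, adjusted p = 0.0604) and Cgnl1 (0.32, adjusted p = 0.0792) did not pass there. The planned count was 19, 18, 25 and 21 without control 1, 2, 3 and 4, and 33, 17, 20 and 13 without high 1, 2, 3 and 4. The count of 54 rested on all 8 arrays. It was 13, 8, 33 and 9 without control 1, 2, 3 and 4, and 36, 7, 34 and 11 without high 1, 2, 3 and 4, and it was 2 with the dimmer probe sets left out and 10 with 1 probe set per gene.

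Genes of lipid synthesis lay lower with the 1% diet as a group. Of the 20 varying members of the fatty acid and triglyceride synthesis list, 18 lay lower, with a median change of −0.73 log2 (camera adjusted p = 1.67e-05, and adjusted p = 0.518 with an estimated correlation). The list's mean on high 4 was 10.34, near the 10.35 of control 4, the lowest control, while the other high arrays lay from 9.30 to 9.77. It differed by −0.98 between the diets, by −0.79 without control 2 and by −1.20 without high 4. None passed over all varying probe sets with limma, 11 had an unadjusted p under 0.05 and lay lower, and 10 passed adjusted over the list alone. With the Gapdh 3-prime minus 5-prime difference added to the fit, the median of this list was −0.50 and 4 members had an unadjusted p under 0.05. The 10 included Elovl6, a fatty acid elongase, at −2.25 ± 0.52 (adjusted p = 0.0605), Pnpla3, a lipid hydrolase induced by feeding, at −5.22 ± 1.39 (0.0856), Mid1ip1, an activator of acetyl-CoA carboxylase, at −1.05 ± 0.29 (0.0951) and Me1, malic enzyme, at −1.96 ± 0.61 (0.129). Of 16 members of cholesterol biosynthesis, 15 lay lower, with a median of −0.56 (adjusted p = 0.00309, and adjusted p = 0.518 with an estimated correlation). None passed, 3 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The mevalonate pathway enzymes Pmvk and Idi1 were at −0.73 ± 0.21 and −0.73 ± 0.30, Sqle, squalene epoxidase, at −0.66 ± 0.29 and Hsd17b7 at −0.43 ± 0.21.

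Of 15 varying genes of glycolysis and glycogen, 13 lay lower with a median of −0.22 (adjusted p = 0.0287, and adjusted p = 0.477 with an estimated correlation). The glycolytic enzymes Tpi1, Eno1, Gpi and Pgam1 were at −0.37 ± 0.10, −0.42 ± 0.17, −0.52 ± 0.22 and −0.17 ± 0.08, 5 members had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. This list was not called without control 2, control 3, high 1 or high 3 (adjusted p 0.0511, 0.0547, 0.0504 and 0.0703). Of 19 phase II and NRF2 target genes, which handle electrophiles and oxidants, 18 lay lower with a median of −0.25 (adjusted p = 0.0135, and adjusted p = 0.518 with an estimated correlation). Srxn1 was at −0.78 ± 0.24, the glutathione transferases Gsta3 and Gstm1 at −2.01 ± 0.70 and −0.20 ± 0.08, and Gclc, of glutathione synthesis, at −0.80 ± 0.30. In this list 6 had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. The list's mean differed by −0.53, and by −0.27 without control 1, and it was not called without control 1 (adjusted p = 0.0794) or high 1 (0.0849).

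Genes of proliferation and of protein turnover lay lower too. In the cell cycle list 11 of 12 lay lower with a median of −0.37 (adjusted p = 1.20e-04, and adjusted p = 0.477 with an estimated correlation). The mitotic cyclin Ccnb1 fell by 0.43 ± 0.09 (adjusted p = 0.0485), and 7 members passed adjusted over the list alone, among them Ccna2 at −0.77 ± 0.19, Cdkn3 at −1.05 ± 0.28 and the mitotic kinase Cdk1 at −1.11 ± 0.30. The mean of Ccnb1 went from 7.03 to 6.60 log2, close to the arrays' median of 6.59. All 12 varying proteasome genes lay lower (adjusted p = 0.0112, and adjusted p = 0.518 with an estimated correlation). Psmc6 fell by 0.30 ± 0.06 (adjusted p = 0.0486) and was the 1 member to pass adjusted over the list alone, while Psma4, Psma2 and Psma5 were at −0.30, −0.33 and −0.13. Ccnb1 and Psmc6 passed in 0 of 8 fits with an array left out (limma, adjusted p from 0.0619 and 0.0630). The proteasome list was not called without control 1 (adjusted p = 0.0510) or high 2 (0.0736). All 11 varying ribosomal protein genes lay lower, by a median of −0.11 (adjusted p = 0.00791, and adjusted p = 0.518 with an estimated correlation). Rpl11, Rpl3, Rps6 and Rpl5 were at −0.18, −0.29, −0.21 and −0.17, 4 had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. Their mean differed by −0.13, and by −0.086 without control 1, where the list was not called (adjusted p = 0.0837).

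Bile acid, cytochrome P450 and stellate cell genes lay higher. Of 18 genes of bile acid synthesis and sterol export, 15 lay higher with a median of 0.22 (adjusted p = 0.00309, and adjusted p = 0.477 with an estimated correlation). Abcb4, the canalicular phospholipid transporter, was at 0.96 ± 0.21 (adjusted p = 0.0579) and was the 1 member to pass adjusted over the list alone. Cyp27a1, the sterol 27-hydroxylase, was at 0.40 ± 0.12, the bile salt export pump Abcb11 at 0.22 ± 0.08 and the peroxisomal oxidase Acox2 at 0.51 ± 0.20. Of 18 cytochrome P450 genes 15 lay higher with a median of 0.13 (adjusted p = 0.0112, and adjusted p = 0.477 with an estimated correlation). Cyp2d3 was at 0.20 ± 0.07, the xenobiotic receptor CAR, Nr1i3, at 1.16 ± 0.41, the P450 reductase Por at 0.52 ± 0.23 and Cyp1a2 at 0.79 ± 0.41, with 3 at an unadjusted p under 0.05 and 0 passing, also adjusted over the list alone. Of 14 measured markers of stellate cells and fibroblasts, 5 vary and the rest are flat, with no measured change. All 5 lay higher with a median of 0.21 (camera adjusted p = 0.0449, and adjusted p = 0.518 with an estimated correlation). Colec11, Lum, Reln and Dcn were at 0.21, 0.65, 0.16 and 0.23, 1 had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. The stellate list was called without control 4 or high 2 and not without any of the other 6 arrays (adjusted p from 0.0511 to 0.149). Of the 10 lists called in this comparison, 8 could be tested with the dimmer probe sets left out, and 5 of these were called. The P450, phase II and proteasome lists were not (camera adjusted p 0.0938, 0.0987 and 0.0563).

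These 10 called lists of 26 tested among varying genes came from camera with the preset correlation. With an estimated correlation 0 were called and 1 had an unadjusted p under 0.05, and with fry 0 were called (lowest adjusted p = 0.0654) and 6 had an unadjusted p under 0.05. Over all measured genes 13 of 32 lists were called, which were these 10 plus oxidative phosphorylation (lower, adjusted p = 0.0122), extracellular matrix (higher, 0.0226) and endothelial cell markers (higher, 0.00426). In these 3, 14 of 26, 7 of 22 and 3 of 11 measured members vary and the rest are flat, with no measured change. Whether the added calls rest on the flat or the varying members was not tested. With an estimated correlation 1 of the 13 held, the cell cycle (camera adjusted p = 0.0230), and fry called 0. In the cell cycle list 12 of 25 measured members vary and the rest are flat. Among its varying members the estimated correlation was 0.376 and the same test gave an adjusted p of 0.477. Without control 1, 6 of 26 lists were called. A contrast of clock genes was chosen after the data were seen. It includes Nr1d1, which rose, so it is no separate support for a clock difference between 1% wakame and control. The mean of 8 genes of the Nr1d1 and Dbp arm minus that of 4 genes of the Npas2 and Cry1 arm was −1.54 ± 0.18 in control, −0.72 ± 0.63 in low and −0.45 ± 0.19 in high (SD, n = 4; high against control p = 0.0286, exact).

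**Figure D2:**
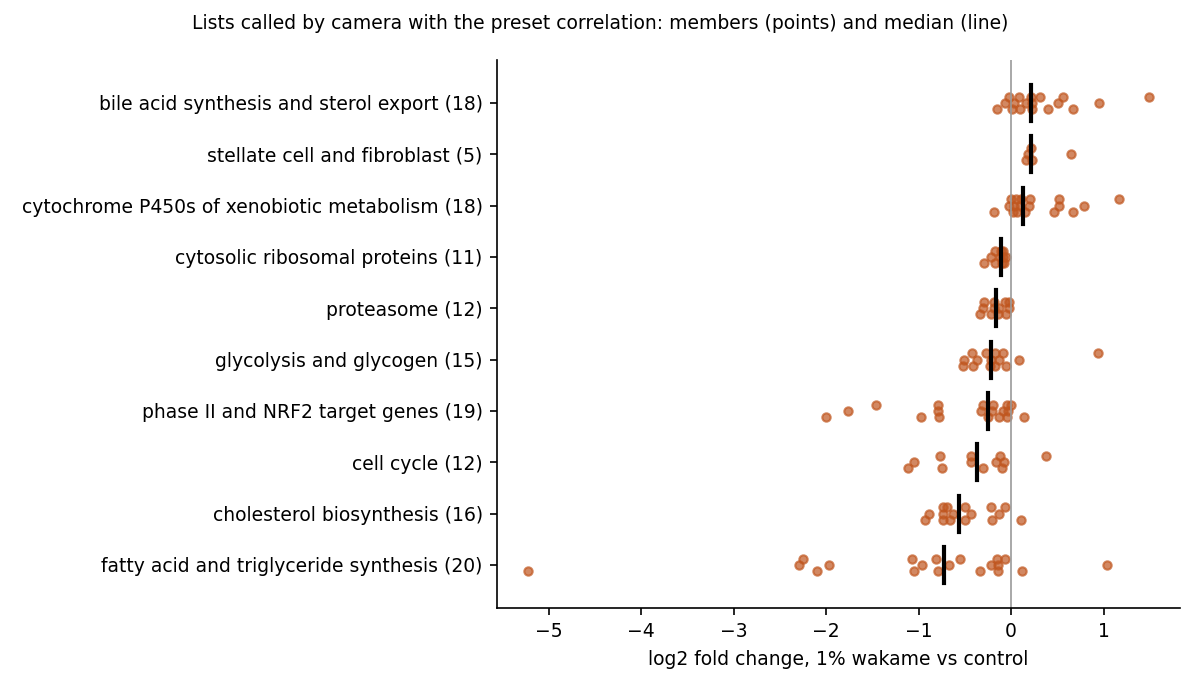
Log2 fold changes of the varying members (points, their number in brackets) and the median (line) of the 10 lists that camera called at the preset correlation for 1% wakame against control. Fatty acid and triglyceride synthesis had the lowest median, −0.73, and none of the 10 calls held with an estimated correlation.

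The other lists were not called among varying genes for 1% wakame against control. In the circadian clock list, 9 of 15 lay higher (adjusted p = 0.270). Nr1d1 rose, Cry1 was at −0.64 ± 0.16, and 6 members passed adjusted over the list alone. In the growth hormone dependent and sex-biased list, 10 of 19 lay higher (adjusted p = 0.946), with Bcl6 and Socs2 the 2 that passed, over all varying probe sets and adjusted over the list alone. Of 10 metal handling genes (adjusted p = 0.426), the metallothioneins Mt1 and Mt2A were at 0.47 ± 0.11 and 3.67 ± 1.01 and passed adjusted over the list alone, and neither passed over all varying probe sets (adjusted p = 0.0622 and 0.0950). In acute phase and inflammation (adjusted p = 0.187) Il6r, the interleukin-6 receptor, was at 1.30 ± 0.34 and Il1r1 at 0.62 ± 0.22. In the unfolded protein response and heat shock list (adjusted p = 0.662) the stress factor Atf4 was at −0.49 ± 0.12 and Herpud1 at 1.03 ± 0.31. Il6r and Atf4 each passed adjusted over their list alone.

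Fatty acid oxidation had 7 of 13 members higher (adjusted p = 0.882), with Cpt1a at 0.64 ± 0.30 and Ehhadh at −0.40 ± 0.23. Other PPARalpha targets and ketogenesis (adjusted p = 0.849) held Creb3l3 at 0.35 ± 0.13 beside Me1, which did not pass over this list alone or over that of thyroid hormone responsive genes. Gluconeogenesis (adjusted p = 0.0725) held Slc37a4 at 0.40 ± 0.14 and Pck1 at 0.57 ± 0.22. Lipoproteins (adjusted p = 0.233) held Apoc2 at 0.10 and Apoc1 at 0.06, and amino acid catabolism (adjusted p = 0.233) Glul at 0.77 ± 0.25 and Tdo2 at 0.49 ± 0.19. Interferon response (adjusted p = 0.426) held Psmb9 at −0.67 ± 0.27, oxidative phosphorylation (adjusted p = 0.196) Sdhd at −0.14, and extracellular matrix (adjusted p = 0.287) Lum at 0.65 and Lox at 1.13 ± 0.66. Thyroid hormone responsive genes (adjusted p = 0.688, tested as higher) had a median of 0.19 and a mean of −0.11, of opposite sign, with Me1 and Gpd2 at −1.96 and 0.19. Hepatocyte markers (adjusted p = 0.576, tested as higher) had a median of 0.02 and a mean of −0.01, with Tat at −1.04 ± 0.48 and Cyp2e1 at 0.67 ± 0.35. Kupffer cell markers (adjusted p = 0.499) held Cd14 at 0.35 ± 0.29.

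The marker lists of endothelial cells, cholangiocytes, lymphocytes, neutrophils and mast cells, erythroid cells, and adipose, muscle and pancreas had 3, 1, 3, 1, 2 and 2 varying members, too few to be tested there. The medians of these members for 1% wakame against control were 0.12, −0.11, −0.01 (mean 0.04), 0.01, 0.09 and −0.02. As their other members are flat, nothing is said here of these cell types.

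Of the 27 genes fixed by name, 21 had a probe set and 16 of these varied. With limma 0 passed in any comparison. At an unadjusted p under 0.05 were 6 for the 1% diet against control, 5 for the 0.1% diet against control and 1 between the wakame diets, and 1, 2 and 0 passed adjusted over the list alone. For the 1% diet Fasn, fatty acid synthase, was at −2.30 ± 0.72 (adjusted p = 0.131), the lipogenic regulator Srebf1 at −1.07 ± 0.37, Acaca at −0.79, Thrsp at −0.81, Pdk4 at −0.71, Scd at −0.16 and Nqo1 at −0.98. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.31 ± 0.56, Cyp8b1 at −0.16, Cyp4a1 at 0.09 and Dio1 at −0.19. The probe sets of Acadm, Ppara, Ucp2, Fgf21 and Cyp1a1 were flat, so no change was measured for them in either direction. The signs of Cyp4a1, Cyp7a1, Cyp8b1 and Dio1 turned when one array was left out.

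The comparison of the 0.1% diet with control asks what the smaller dose changed. The probe sets that fell had no gene named here. They were 1391718_at, which fell by 1.76 ± 0.23 log2 (adjusted p = 0.0363), and 1391407_at, which fell by 1.64 ± 0.23 (adjusted p = 0.0440), each lower in 4 of 4 rats, and with the 1% diet, against the same control arrays, they fell by 2.26 and 2.55. The named genes with the smallest p did not pass. Hycc2 was at 0.75 ± 0.12 and Asap2 at −0.36 ± 0.06 (both adjusted p = 0.0778), with Rtp3, a receptor transport protein, at −1.51 ± 0.26 (0.0778). The aminopeptidase Aopep was at 0.57, Gucd1 at 1.04, Mid1ip1 at −1.44, the trypsin inhibitor Spink1 at −1.68, Baiap2l1 at 0.66, the proteoglycan Sdc4 at 0.99 and the actin-binding Svil at −0.49 (adjusted p from 0.138 to 0.190).

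In total 2 of 3240 varying probe sets passed for 0.1% wakame against control, and 371 had an unadjusted p under 0.05. The diets did not overlap in 190 (5.86%, chance 2.86%). The count was 1 without control 1 and 0 without control 3, control 4, low 3 or low 4, and 0 with the dimmer probe sets left out. The planned fit called 5, all with changes below 1e-06 log2. Of the 10 genes the rule took from it 7 were such flat changes, and Asap2, Hycc2 and Nxf1 (0.13, adjusted p = 0.361) did not pass there. The planned count was 12, 11, 21 and 17 without control 1, 2, 3 and 4, and 15, 15, 19 and 12 without low 1, 2, 3 and 4.

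Camera called 6 of 26 lists for the 0.1% diet. Fatty acid and triglyceride synthesis lay lower in 17 of 20 members, with a median of −0.45 (adjusted p = 0.00169, and adjusted p = 0.520 with an estimated correlation). Mid1ip1 was at −1.44 ± 0.29 and passed adjusted over the list alone, the 1 member to do so, with Elovl6 at −1.41 ± 0.52, Agpat2 at −0.14 and Lpin1, a phosphatidate phosphatase, at 1.91 ± 0.58. Without control 2 this list was not called (adjusted p = 0.0520). Cell cycle genes lay lower in 12 of 12 (adjusted p = 6.45e-05, and adjusted p = 0.480 with an estimated correlation), with Ccna2, Ccnb1, Mki67 and Ccnb2 at −0.65, −0.30, −0.42 and −0.62 and 6 members passing adjusted over the list alone. Glycolysis and glycogen lay lower in 12 of 15 (adjusted p = 0.00305, and adjusted p = 0.455 with an estimated correlation), with Gpi, Tpi1, Pklr and Gbe1 at −0.67, −0.32, −0.64 and −0.18. In that list 5 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (limma).

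The lists that lay higher with the 0.1% diet were bile acid synthesis and sterol export, amino acid catabolism and gluconeogenesis. Bile acid genes lay higher in 13 of 18 (adjusted p = 0.00305, and adjusted p = 0.455 with an estimated correlation), with Abcb4 at 0.81 ± 0.21, the nuclear receptor SHP, Nr0b2, at 1.93 ± 0.59, Cyp7a1 at 1.49 ± 0.56 and Acox2 at 0.51 ± 0.20. Amino acid catabolism lay higher in 20 of 24 (adjusted p = 0.00353, and adjusted p = 0.515 with an estimated correlation), with Tdo2, Hal, Oat and Kmo at 0.55, 0.36, 1.06 and 0.22. In these lists 5 and 1 members had an unadjusted p under 0.05 and 0 passed adjusted over either list alone (limma). Gluconeogenesis lay higher in 10 of 12 (adjusted p = 0.0101, and adjusted p = 0.515 with an estimated correlation). Igfbp1, an insulin-repressed binding protein, was at 2.71 ± 0.69 and Pck1, of gluconeogenesis, at 0.73 ± 0.22, the 2 that passed adjusted over the list alone, with Slc37a4 at 0.34 and Ppargc1a at 0.24. The mean of gluconeogenesis differed by 0.51, and by 0.32 without control 1. Bile acid genes were not called without control 2 (adjusted p = 0.0520) or with the dimmer probe sets left out (0.0965), nor gluconeogenesis without low 1 (0.0841). With the dimmer probe sets left out, 5 of the 6 lists could be tested. With an estimated correlation 0 lists were called and 2 had an unadjusted p under 0.05, and with fry 0 and 3. The count of lists was 10 without control 3 and 10 without low 3, and over all measured genes it was 10 of 32, with 6 called without control 1 and 6 without low 4. Nqo1 and Gstm1 of the phase II list, which was not called (adjusted p = 0.0902), were at −1.82 ± 0.42 and −0.28 ± 0.08 and passed adjusted over the list alone.

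The direct comparison of the wakame diets asks whether the doses differed. No gene passed between 1% and 0.1% wakame with limma (0 of 3240, smallest adjusted p = 0.246), and 219 had an unadjusted p under 0.05. Spink1 was at 1.92 ± 0.35 higher with 1% wakame (adjusted p = 0.246) and did not pass. The next smallest p were those of Arhgap42 at 0.35, Krcc1 at −0.39, Syne1 at 0.62, Foxp1 at 0.76, Phtf2 at 0.79, Fchsd2 at 0.70, Socs2 at −1.14 ± 0.27, Masp1 at 0.42 and Clint1 at −0.33 (all adjusted p = 0.420). The diets did not overlap in 122 of 3240 (3.77%, chance 2.86%), and without the variance trend 0 passed. The count was 1 without low 1. The planned fit called 6, all with changes below 1e-06 log2, and of the 10 genes the rule took from it 9 were flat, with Ankrd13c at −0.06 not passing. Its count was 20, 16, 16 and 15 without low 1, 2, 3 and 4, and 19, 16, 14 and 11 without high 1, 2, 3 and 4. Ribosomal protein genes lay lower with 1% than with 0.1% in 11 of 11, by a median of −0.09 (camera adjusted p = 0.0127, and adjusted p = 0.885 with an estimated correlation), with Rpl11, Rps6, Rpl7 and Rpl4 at −0.14, −0.16, −0.12 and −0.09. The list was not called without low 2, low 3 or high 1 (adjusted p 0.0814, 0.0690 and 0.0961), nor after quantile normalization (0.0574). In this list 1 member had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (limma). This was the 1 list called of 26, and 1 of 32 over all measured genes. The count over varying genes was 0 without low 3 or high 1, 3 without low 4, 4 without high 3 and 5 without high 4, and over all measured genes it was 4, 2 and 6 without low 2, 3 and 4, and 2, 2, 3 and 6 without high 1, 2, 3 and 4. With an estimated correlation and with fry 0 lists were called, and 0 had an unadjusted p under 0.05 with either.

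Any difference among the 3 diets was found for 6 varying probe sets (F-test in limma), which were Asap2 (adjusted p = 0.0304), Hycc2 (0.0245) and 4 with no gene named here. All 6 also changed between 1% wakame and control. The count was 3, 2, 2 and 3 without control 1, 2, 3 and 4, 11 and 10 without low 1 and 3, and 19, 3, 3 and 2 without high 1, 2, 3 and 4. The planned fit called 12, of which 3 had a change of at least 0.1 log2, and 19, 18, 25 and 20 without control 1, 2, 3 and 4, 27, 26, 28 and 22 without low 1, 2, 3 and 4, and 37 and 24 without high 1 and 2.

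Changes with the 2 wakame diets went in similar directions across genes. The fold changes of low and high against control correlated at 0.685 across all 31042 probe sets, which are not independent replicates. Both comparisons use the same 4 control arrays, and random regroupings of the arrays' deviations from their diet means, with no difference left in, gave a mean correlation of 0.507 (range 0.111 to 0.802). The covariance was 0.0128 against a simulated mean of 0.00488 (highest 0.00893), a difference of 0.00789. With the controls split in 2 so that no array was shared, the correlation was 0.395 and the covariance 0.00878 (means of 6 splits), against at most 0.00401 in 100 regroupings, whose highest correlation was 0.274.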

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

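The tests on bright flat probe sets, on spiked RNA, on clock genes and with Gapdh were chosen after the results they test were seen, as were the margins for spread in the verdicts. Arrays were compared within each diet by Dixon's test for a value far from the other 3. It marked 18 of 258 groups of 4 values, where about 1 in 20 would be marked by chance (12.9). The array high 1 held 5 of the 18 and low 4 held 3.

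Among genes that changed with the 1% diet, Onecut1 was at 12.23 log2 on control 4, against 10.91 to 11.07 on the other controls. Sh3bp5 was at 10.09 on high 3 (others 10.78 to 10.86), Birc2 at 8.71 on high 1 (8.00 to 8.08) and Hacd3 at 7.95 on high 3 (7.47 to 7.53). Pank3 was at 7.18 on low 2 (7.03 to 7.05) and at 7.12 on high 1 (6.91 to 6.94), Zfp68 at 7.35 on low 2 (7.19 to 7.22) and Krcc1 at 8.59 on high 4 (8.37 to 8.40). Among genes that did not pass, Fchsd2 was at 9.05 on low 3 (8.64 to 8.66), Thrsp at 12.58 on high 4 (10.48 to 10.69), Dio1 at 7.31 on high 1 (7.08 to 7.11), Nqo1 at 7.51 on high 1 (9.19 to 9.53) and Mt1 at 6.55 on low 3 (6.79 to 6.80).

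Among means of lists, cholesterol biosynthesis was at 8.61 on low 4 (others 9.47 to 9.63), the circadian clock at 7.88 on low 4 (7.59 to 7.63), the cell cycle at 7.04 on low 4 (7.17 to 7.19) and stellate cell markers at 8.58 on control 4 (8.21 to 8.24). The second principal component was at −11.98 on high 1, with the other high arrays from −1.10 to 0.18.

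The flatness of 27802 of 31042 probe sets was weighed first. Some spiked RNAs, which do not come from the liver, had flat beside varying probe sets (2 of 8 transcripts, bioC and cre), so RNA levels that do not differ between livers cannot be the whole cause. Too little signal may contribute for many, since only 4.25% of flat probe sets (1182) were brighter than the median of the varying ones. For these 1182 it stays open too, because brightness compares different probe sets and no background was available. Spiked probe sets that were flat, of bioC (9.88 and 9.99) and cre (13.52), argue against it for those. Varying ones of bioC lay at 9.15 and 9.42, and of cre from 12.96 to 13.79. Low signal alone would not bring 12 separate arrays to an SD below 1e-06, as in 27627 probe sets. A step in the computation of the values is therefore likely involved. Whether it was the summarisation by the authors stays open. Of genes with a varying and another probe set, 13.0% had a flat one at least as bright as the brightest varying one (114 of 875).

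For the lower values of fatty acid and triglyceride synthesis genes with the 1% diet, RNA quality stays open and cannot be told apart from diet. With the Gapdh 3-prime minus 5-prime difference in the fit 67.9% of the list's median was kept (55.6 to 89.0% leaving out each array), and with that of Actb, which differed less between these diets, 112% (96.5 to 122%). A lower share of hepatocytes as the whole cause would lower hepatocyte markers by about the list's median of −0.73, and the 7 varying ones had a median of 0.0158, though markers of Kupffer cells (median 0.09) and stellate cells (0.21) lay higher. The hour of tissue collection could contribute, since the clock arms lay 1.08 log2 apart between high and control (exact p = 0.0286, the smallest possible). Diet can move the clock as well and stays open beside the hour. Neither the hour nor the fasting state of each group is given in the sources used here. Feeding state at collection was not tested and stays open too. A state that differs between rats whatever the diet cannot be told apart with 12 arrays, since within diets the list's mean and Bcl6 correlated at r = −0.130 (permutation p = 0.746; rho −0.119, p = 0.773; r = 0.034 without the 2 farthest arrays).

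The joint direction of the fold changes of both wakame diets was weighed last. Shared control arrays raise such a correlation by themselves. With no control array shared (mean of 6 splits) the covariance was 0.00878, larger than in 100 of 100 regroupings (highest 0.00401), which argues against the shared arrays as the whole cause. A response common to both diets may remain, and so do cage and hour of collection, which were not tested for this pattern.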

How the results depend on the processing

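The fit on varying probe sets, its alternatives, the limits on SD and on the size of a change, and the lists among varying genes were chosen after the data were seen; the other alternatives were planned. Signal over background was not available, so brightness stood in for it. The causes of the differences below were not tested, except that leaving out arrays or probe sets makes the data smaller and adjusted p under 0.10 is a looser threshold.

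In the planned fit the counts for high against control, low against control, high against low and any diet were 9, 5, 6 and 12. They were 3, 0, 0 and 0 after quantile normalization and 3, 0, 0 and 0 with arrays centred on their median (limma; unadjusted counts at p under 0.05 were 2131, 1634, 1132 and 1608 in the planned fit itself). With 1 probe set per gene they were 2, 2, 1 and 2, and with changes of at least 0.1 log2 alone 3, 0, 0 and 3. On varying probe sets alone they were 54, 2, 0 and 6. With the dimmer probe sets (below the median) left out, high against control gave 15 and high against low 3. With only the 8 arrays compared the 3 comparisons gave 56, 40 and 31, and at an adjusted p under 0.10 high against control gave 19. Leaving out each array gave 13 to 33, 11 to 21, 11 to 20 and 14 to 37.

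In the fit on varying probe sets (54, 2, 0 and 6), leaving out the dimmer probe sets gave 2 for high against control, 0 for low against control and 2 for any diet, and 1 probe set per gene gave 10, 0 and 0. Only the 8 arrays compared gave 28 and 0 for high and low against control, and robust eBayes gave 29 for high against control. Array weights gave 1 for low against control. An SD above 0.1 gave 13 for any diet. At an adjusted p under 0.10 the counts were 149, 6 and 55 for high against control, low against control and any diet. Leaving out each array gave 7 to 36, 0 to 3, 0 to 1 and 2 to 19.

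With the replicate number as a block, the varying fit gave 12 for high against control, 0 for low against control and 1 for any diet. The numbers do not pair the arrays: 0 of 12 same-numbered pairs deviated together with a correlation above 0.1 (−0.115 to 0.0924), and 2 correlated best with their own number. Under the replicate block 9 of the 10 lists called for high against control were still called.

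For gene lists over all measured genes, camera with the preset correlation called 13, 10 and 1 for high against control, low against control and high against low. Camera with an estimated correlation called 1, 0 and 0, and fry 0, 0 and 0. Camera on ranks called 3 and quantile normalization 8 for high against low. Leaving out each array gave 6 to 14 for low against control and 1 to 6 for high against low. Among varying genes the counts were 10, 6 and 1. Camera with an estimated correlation gave 0, 0 and 0, and fry 0, 0 and 0. For high against low, camera on ranks gave 3 and quantile normalization 0, and for high against control leaving out the dimmer probe sets gave 6. Leaving out each array gave 6 to 10, 5 to 10 and 0 to 5.

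The correlation of the fold changes of low and high was 0.685, and 0.586 to 0.739 leaving out each array. Of 28 named genes called for high against control, all 28 were called again with 16 added before log2, after centring, after quantile normalization and without the variance trend. Of the 28, 21 were called with array weights, 25 and 23 at an SD above 0.05 and 0.1, 15 with robust eBayes, 12 with only the 8 arrays, 5 with the block and 1 in the planned fit of all probe sets. Without control 1, 2, 3 and 4 it was 4, 4, 16 and 3 of the 28, and without high 1, 2, 3 and 4 it was 12, 3, 16 and 5. Where fewer could be tested, 1 of 8 was called with the dimmer probe sets left out and 10 of 22 with 1 probe set per gene. None of the 28 changed direction in any alternative run (0 reversed). For most alternatives this was set in advance and is no support. The 2 diets did not overlap for any called probe set, so leaving out an array could not turn a sign. Other moderation, limits on SD or thresholds leave the fold change as it is. All 10 lists called for high against control were called again with 16 added before log2, on ranks and after quantile normalization.

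Some genes fixed by name that did not pass changed direction when one array was left out. For high against control, Cyp4a1 ranged from −0.093 to 0.32, Cyp7a1 from −0.081 to 0.85, Cyp8b1 from −0.38 to 0.042 and Dio1 from −0.31 to 0.037. For low against control, Cyp4a1 ranged from −0.35 to 0.14 and Thrsp from −0.29 to 0.26. For high against low, Cpt1a ranged from −0.32 to 0.21, Cyp4a1 from −0.048 to 0.45, Pdk4 from −0.46 to 0.20, Acaca from −0.29 to 0.10, Scd from −0.013 to 0.11, Sqle from −0.46 to 0.027 and Cyp8b1 from −0.13 to 0.28. Counting each called gene once per alternative other than the looser threshold, 225 values passed again and 113 did not, and with single arrays left out 63 passed again and 161 did not. For called lists these were 110 and 40, and 115 and 21 with single arrays left out. Of values for genes that were not called, 15 newly passed and 26 changed direction.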

Other observations

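The tests of Bcl6 with Onecut1 and Socs2 were chosen after the values were seen, and the fit and lists on varying probe sets, whose other splits are given below, after the data were seen. Genes of the circadian clock that the report names only in part differed in both directions between the 1% diet and control. Besides Nr1d1, which rose, Nr1d2 was at 1.01 ± 0.25 log2, Tef at 0.63 ± 0.18 and Dbp at 0.93 ± 0.34, and Rora at −0.37 ± 0.09 beside Cry1 at −0.64 ± 0.16 (SE, n = 4 per diet). These 6 passed adjusted over the list alone, and with the 0.1% diet Nr1d1 at 1.21, Nr1d2 at 0.90 and Per1 at 0.51 did so. Between the wakame diets, Tat, an amino acid degrading enzyme induced by glucocorticoids, was at −1.81 ± 0.48. It passed adjusted over the gluconeogenesis list alone and over the hepatocyte markers alone, and not over the amino acid catabolism list alone. In the growth hormone list, Bcl6 at 2.82 ± 0.77 and Socs2 at −1.14 ± 0.27 passed adjusted over the list alone in this comparison, and none of these 3 genes passed over all varying probe sets.

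Values of Bcl6 differed between rats of one diet. With 0.1% wakame it was 7.11 and 7.06 on low 1 and 2 and 10.18 and 10.13 on low 3 and 4. A hypothesis chosen after these values were seen is that a state linked to growth hormone may differ between rats of one diet, in which case Onecut1 and Socs2, which growth hormone raises, would be lower where Bcl6 is higher. Within diets Bcl6 and Onecut1 correlated at r = −0.731 (n = 12, permutation p = 0.0175, adjusted over 3 relations 0.0525; rho −0.797, p = 0.0234; r = −0.69 without the 2 farthest arrays). Bcl6 and Socs2 correlated at r = −0.681 (p = 0.0429, adjusted 0.0643; rho −0.657, p = 0.0768; r = −0.61 without the 2 farthest). Each r pools the diets, and among controls the lowest Bcl6 (5.57) and the lowest Onecut1 (10.91) were both on control 3. Rats shared cages, the cage of each array is not given, and the permutations treat rats as independent. The adjusted values miss 0.05, growth hormone was not measured, and a state of this kind does not exclude an effect of diet.

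The arrays were also split in all other ways into groups of the same sizes. For varying probe sets and high against control, the real split gave 54 and the highest other split 1. So 1 of 35 splits, the real one, gave as many, which is the smallest share possible. This argues against a chance division of the arrays, though not against chance differences between cages. The fit was chosen after its counts were seen, and no adjustment was made for the number of split tests. For any diet the real value was 6, the highest other 5, and 1 of 100 gave as many. With so small a margin and only 100 groupings drawn, chance is not excluded there. Nor can chance be excluded for low against control (2, highest other 2, 2 of 35) or high against low (0, highest other 4, 35 of 35, with 219 at an unadjusted p under 0.05 in limma). In the planned fit chance cannot be excluded for high against control (9, highest other 15, 8 of 35), low against control (5, highest other 12, 19 of 35), high against low (6, highest other 14, 18 of 35) or any diet (12, highest other 17, 28 of 100).

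For gene lists chance cannot be excluded in any comparison. Over all measured genes the real and highest other counts were 13 and 15 for high against control (2 of 35 splits), 10 and 16 for low against control (7 of 35) and 1 and 10 for high against low (33 of 35). Among varying genes they were 10 and 14 (5 of 35), 6 and 13 (14 of 35) and 1 and 7 (32 of 35). Some splits of the high and low arrays called several times the real count. This points to a structure of these arrays other than diet or to genes that vary together, and these were not tested apart. The estimated correlation ran from −0.036 in the metal handling list to 0.646 in the proteasome list, against the preset 0.01.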
